A study of Acropora cervicornis with 12 samples.

How the data were processed

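The series measured messenger RNA by sequencing in the staghorn coral Acropora cervicornis, a reef-building coral of the Caribbean and Florida whose tissue houses single-celled algal symbionts. The libraries therefore hold RNA of the coral host and of the symbiont, and may hold RNA of other organisms of the tissue. There were 12 libraries, 1 for each combination of 3 temperatures, 2 collection seasons and 2 nurseries. Each library pooled RNA from 7 genets (host genotypes), 84 RNA extracts in all, per the labels' protocols. A branch of about 9 cm was cut into 3 fragments, and each fragment was held for 1 h at 35 °C (hot), 10 °C (cold) or the ambient temperature of the season (24 to 28 °C) before preservation. Collections were in June 2011 (summer) and February 2012 (winter). Each season is thus a single collection, and season cannot be told apart from the date or handling of that collection. Stranded oligo(dT)-selected libraries were read as 150 bp single reads over 3 lanes.

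The deposited values are estimated counts (expected counts) of reads per assembled transcript contig, made by the authors. Reads were trimmed, aligned and quantified with Trimmomatic 0.3, Bowtie2 2.1.0 and eXpress 1.5.1, per the submitters' processing notes, which list the tools without their settings. The estimated counts are whole numbers in all deposited tables, so the rounding applied before the count tests changed no value. No genome build applies, since contigs and not genome positions were counted. The deposited tables hold 95389 contigs in all, 22772 of them also in a host table and 21094 in a symbiont table, with the same counts in both places. The other 51523 contigs are in neither, and how contigs were assigned to a partner is not given in the sources used here. An estimator such as eXpress divides reads among similar contigs, so contigs of near-identical copies are uncertain. The files do not pair the contig identifiers with gene names and no annotation was used here, so contigs are named by identifier, and none of the 22 gene lists fixed before the data were examined could be tested, markers of cnidocytes, neurons and germ cells included. Strand was kept by the kit, and whether the counting used it is not given in the sources used here.

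Total counts per library over all contigs ran from 33847106 to 48244845, host totals from 13491979 to 23180850 and symbiont totals from 1975687 to 8792394. The median symbiont contig had 61 to 113 counts in the ambient libraries and 10 to 27 in the hot ones, so their relative counting error is largest in the hot libraries. No 2 libraries of one temperature agreed within counting noise (lowest chi-square per host contig 47.8), and all were kept as separate replicates. A library is a pool, so the spread between libraries holds differences between pools, seasons and nurseries, and not between single corals.

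Host and symbiont tables were tested separately with edgeR 4.0.16 in R 4.3.3. Contigs were kept by filterByExpr with the temperature as group (21213 host and 20656 symbiont contigs), scaled by TMM factors within the partner's table, and fitted with the robust quasi-likelihood model with terms for season, nursery and temperature over all 12 libraries (7 residual degrees of freedom). The interactions of temperature with season and with nursery were tested as 2 further models. A contig was called when its Benjamini-Hochberg adjusted p was under 0.05. Standard errors (SE) of log2 fold changes came from the fold change and its F statistic. Contigs are named by a rule set before the data were examined: among called contigs with a mean of at least 1 CPM (the usual library-size-scaled count) and a change in the same direction in every matched pair of libraries, the 2 with the largest rise and the 2 with the largest fall in each comparison. On simulated counts with 200 changed contigs among the 21213 host contigs, the hot against ambient test recovered 37% of those changed 4-fold and 56% of those changed 8-fold, and 2.11% of its calls were false. For winter against summer the shares were 50% and 69%, with 3.25% false. Among the 20656 symbiont contigs the hot against ambient test recovered 41% and 64%, with 2.78% false, and the winter against summer test 55% and 67%, with 6.15% false. The simulated libraries were independent and apart from the changed contigs held no differences between seasons, nurseries or pools. These rates therefore need not hold for the real libraries.

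The ratio of symbiont to host counts was compared on the log2 scale with two-sided exact permutation tests that flipped the sign of matched pairs, 4 pairs for temperature and 6 for season or nursery. The share of variance in log2 CPM (prior count of 2) was tested with 10000 permutations of the libraries. The hot and cold comparisons share the ambient libraries, so their overlap is given beside 20 simulations of unchanged groups, beside the overlap of independent lists and with the ambient libraries divided between the comparisons.

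The labels conflict on the nursery. Library codes end in 1 or 2, and 1 goes with Miami and 2 with the Lower Keys in the ambient and hot libraries, while in the 4 cold libraries 1 goes with the Lower Keys and 2 with Miami. One ambient winter library also carries code number 1 in its description and 2 in the column of the count table. The nursery labels were used as deposited in the fixed design. The code number was used in place of the nursery in an alternative chosen after the data were seen. Replicate numbers were given in accession order, which makes them follow season and code number, and they were not used to pair libraries. Pairing in the fixed design comes from the season and nursery labels, since the fragments of a branch went to the 3 temperatures. Host deviations from the temperature means correlated between ambient and hot libraries of the same season and nursery label (mean 0.38 over 4 pairs, lowest 0.20). With a cold library in the pair, they did so between libraries of the same code number (mean 0.42 over 8 pairs, lowest 0.19) and not of the same nursery label (mean -0.17 over 8 pairs). The check of the pairing thus holds by nursery label only for ambient and hot libraries.

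The alternatives were DESeq2 size factors in the same fit, library totals without further factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 4 libraries, a block of season-by-nursery strata, the compared factor as the only term, only the 8 libraries of the compared temperatures, a log2 fold change of at least 1, a fit without the robust step, and each library left out in turn. Added after the data were seen were the code number as nursery, a block by season and code number, only the ambient and hot libraries, scaling by the total over all contigs, and pairs by season and code number for the symbiont to host ratio. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The Upper Keys nursery and the other collections named in the labels were not analysed here.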

Results

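RNA was measured in 12 pooled libraries of staghorn coral tissue, 4 at each of 3 temperatures. The 4 libraries of a temperature came from summer and winter collections at an offshore Miami nursery and a Lower Keys nursery, where coral fragments are grown for reef restoration. The question was how a 1 h exposure to 35 °C or 10 °C changed transcript levels against the ambient temperature, and how large the response was beside season and nursery. The ambient libraries held 37038439 to 48244845 counts over all contigs, and the lowest total of any library was 33847106 in the winter cold library labelled Miami. Host contigs held 46.3% ± 3.46 of all counts in the ambient libraries, 61.8% ± 3.48 in the hot and 45.9% ± 5.79 in the cold (SD, n = 4 each). Symbiont contigs held 16.5% ± 2.40, 7.73% ± 2.71 and 16.4% ± 4.66. Contigs in neither table held the rest.

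Heat changed 1288 of 21213 host contigs, with 674 higher and 614 lower than in the ambient libraries by edgeR's quasi-likelihood test. Among them, 122 rose at least 8-fold and 59 fell at least 8-fold, and the median log2 fold change was 1.76 for the risen and -1.50 for the fallen contigs. DESeq2 called 2607, 1217 higher and 1390 lower. The 674 risen contigs held 6.89% ± 1.40 of host counts in the ambient libraries and 33.8% ± 5.64 in the hot libraries, against 6.66% ± 1.36 in the cold (SD, n = 4 each). The 614 fallen contigs went from 3.51% ± 0.41 to 0.95% ± 0.21 of host counts. Contig GASU01082780.1 rose from 4.29 ± 3.12 to 709.1 ± 577 CPM (SD, n = 4 each), a log2 fold change of 7.26 (SE 1.09, adjusted p = 0.0040). GASU01076987.1 rose from 37.0 ± 27.9 to 3756 ± 2270 CPM, a log2 fold change of 6.83 (SE 0.80, adjusted p = 0.0014).

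**Figure D1:**
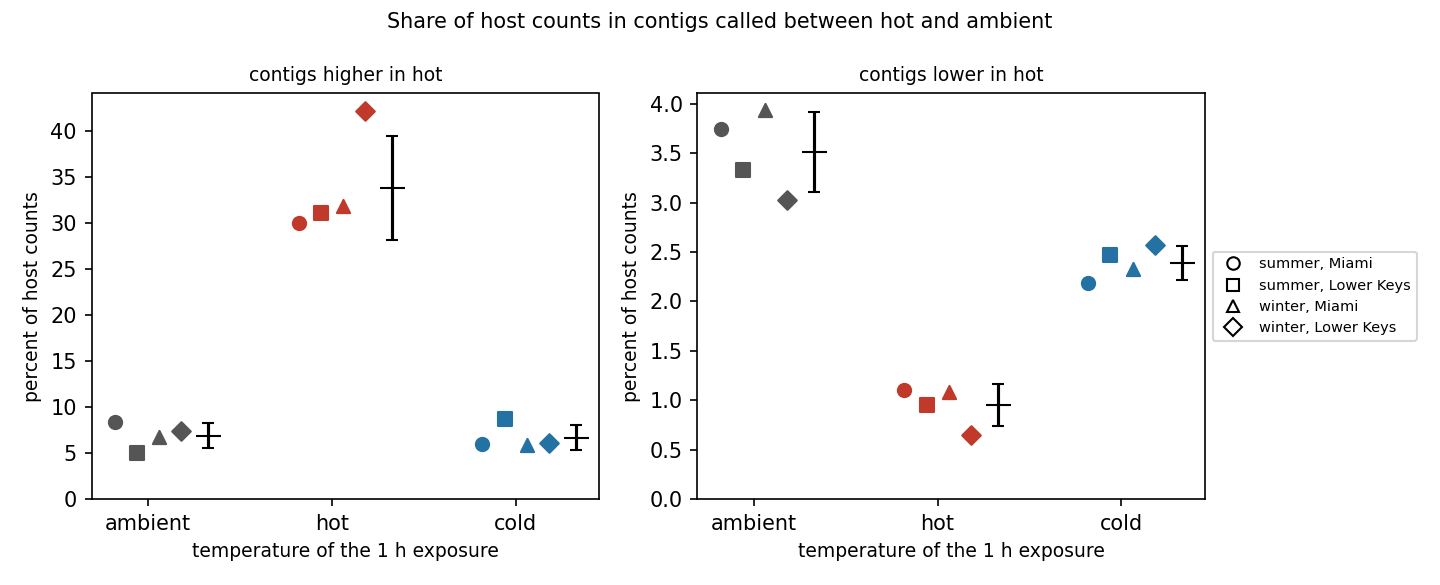
Percent of each library's host counts in the 674 contigs called higher and the 614 called lower in hot than in ambient, by temperature; points are libraries (marker shape gives season and nursery label), bars the mean and SD of 4 libraries. The hot libraries sit between 30.0% and 42.2% for the risen contigs and every ambient and cold library lies at or under 8.69%.

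Among the fallen contigs, GASU01057482.1 had 141 counts over the 4 ambient libraries and 0 over the 4 hot ones, which makes it at least 37.9-fold lower with a floor of 3 counts over the group. GASU01049002.1 had 226 ambient counts and 1 hot count, a 182-fold fall with a 95% counting interval (exact binomial) from 32.4 to 7233. Such intervals and floors cover counting error only. With the season-by-nursery strata as a replicate block the call of GASU01057482.1 ended, while those of the other named contigs of this comparison stayed. Of the 1288 contigs, 1285 moved the same way in all 4 matched pairs, which being called on these libraries favours. Over all tested host contigs the changes in summer and in winter correlated at 0.52 (Spearman). The medians of the risen contigs were 1.72 on the log2 scale in summer and 1.79 in winter, and those of the fallen contigs were -1.41 and -1.54. Calling the contigs on both seasons together favours like medians as well. No host contig passed the test of a temperature by season interaction in edgeR (231 at an unadjusted p under 0.05, where 1061 lie under it by chance alone, and 17 by DESeq2). With so few small p-values that test was conservative, and its lack of calls does not show that the seasons responded alike.

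The balance of rises and falls depended on the scaling. With library totals in place of TMM factors, 4267 contigs were called, 382 higher and 3885 lower, with a median log2 fold change over all contigs of -0.62 against -0.02 with TMM. With the total over all contigs the split was 439 higher and 793 lower. With only the 8 ambient and hot libraries 1666 contigs were called, and without hot replicate 4 (winter, Lower Keys) 429. The season-by-nursery strata as a replicate block gave 882. With the code number in place of the nursery 2607 contigs were called (1315 higher, 1292 lower). A block by season and code number gave 3810 (1890 higher, 1920 lower), and both uses of the code number were chosen after seeing the data.

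Fewer host contigs were called for cold than for heat, and most of them were lower. Of 21213 contigs, 249 were called by edgeR, 38 higher and 211 lower, and 15 of them fell at least 8-fold while none rose as far. DESeq2 called 1123, 308 higher and 815 lower. Among called contigs that met the naming rule, the largest rise was in GASU01091610.1, from 3.57 ± 0.13 CPM in the ambient to 26.3 ± 14.5 CPM in the cold libraries (SD, n = 4 each). Its log2 fold change was 2.71 (SE 0.35, adjusted p = 0.012). GASU01061941.1 rose by 2.41 (SE 0.49, adjusted p = 0.046). GASU01084376.1 fell from 55.1 ± 28.5 to 1.46 ± 1.82 CPM, a log2 fold change of -5.39 (SE 0.89, adjusted p = 0.024). The abundant contig GASU01030213.1 fell from 990.6 ± 430 to 61.7 ± 32.5 CPM, a log2 fold change of -4.07 (SE 0.33, adjusted p = 0.0019). In the hot libraries these named contigs lay on the same side of the ambient mean as in the cold. Their hot means were 8.08 CPM for GASU01091610.1, 1.60 for GASU01061941.1 (ambient 0.75), 17.8 for GASU01084376.1 and 191 for GASU01030213.1. A change particular to cold is thus not shown for them, and both comparisons share the ambient libraries.

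Over all tested host contigs the cold changes in summer and in winter correlated at 0.37 (Spearman). With the season-by-nursery strata as a replicate block, 54 contigs were called, all among the 249, and the calls of GASU01061941.1 and GASU01084376.1 ended. With only the 8 ambient and cold libraries edgeR called 0 (main count 249), and leaving out 1 library gave 14 (without cold replicate 4) to 271 contigs. The nursery labels of the cold libraries conflict with their code numbers, and with the code number in place of the nursery 965 contigs were called (269 higher, 696 lower), all 249 among them. The split of the calls was 36 higher and 85 lower with library totals in place of TMM, and 25 and 63 with the total over all contigs.

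Between the hot and cold libraries 1494 host contigs differed, 977 higher and 517 lower in the hot. DESeq2 called 3073, and leaving out 1 library gave 585 to 1716, with 585 without hot replicate 4, 694 and 708 without cold replicates 3 and 4, and 818 and 923 without hot replicates 2 and 1. GASU01082780.1 had the largest rise among contigs with a mean of at least 1 CPM, a log2 fold change of 7.59 (SE 1.10, adjusted p = 0.0026). GASU01031788.1 reached 12648 ± 5932 CPM in the hot libraries against 375 ± 182 in the ambient and 122 ± 119 in the cold (SD, n = 4 each), a log2 fold change of 7.28 between hot and cold (SE 0.78, adjusted p = 0.00054). Its difference between cold and ambient, a log2 fold change of -1.92, did not pass the test (adjusted p = 0.19). GASU01057482.1 was at least 31.3-fold lower in the hot than in the cold, and GASU01049002.1 was 135-fold lower with a counting interval from 23.9 to 5367. The call of GASU01057482.1 ended here too with the season-by-nursery block. With library totals in place of TMM the split was 465 higher and 6782 lower, at a median log2 fold change of -0.95 over all contigs, and with the total over all contigs 553 higher and 1630 lower. The season-by-nursery block called 1061 contigs. The code number in place of the nursery gave 3195 and the block by season and code number 4461, both chosen after seeing the data.

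A part of the host contigs called for cold was also called for heat. Of the host contigs, 12 were higher and 48 lower in both the hot and the cold libraries, and 10 were called in opposite directions, all 10 higher in the hot and lower in the cold. Independent lists of these lengths would share 1.21, 6.11 and 7.80 contigs. Because both comparisons use the same ambient libraries, 20 simulations of unchanged groups were made in which both share simulated ambient libraries. All 12 libraries were simulated, so traits of the real ambient libraries beyond the fitted season and nursery are not carried over. The simulations gave at most 3 hot and 0 cold calls, so they hold no expected number of shared calls. The log2 fold changes of hot and cold correlated at 0.31 across contigs, under the mean of 0.49 in the simulations, and contigs are not independent replicates. Their covariance was 0.292 beside a simulated mean of 0.266 (range 0.253 to 0.282). With the ambient libraries divided between the comparisons, the correlation lay between -0.23 and 0.09 over the 6 divisions. Over these divisions 0 to 2 contigs were higher in both, 1 to 14 lower in both and 0 to 30 opposite, and the division with 14 lower in both was the one with 30 opposite. The divided comparisons also made fewer calls, between 171 and 688 for heat and between 2 and 297 for cold.

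Few host contigs were called for season when nursery labels were taken as deposited. Of the 21213 contigs 7 were called between winter and summer by edgeR, 3 higher and 4 lower in winter, while 3329 had an unadjusted p under 0.05. The 6 libraries of a season share corals across temperatures and are not 6 independent pools, so the season test overstates the replication. GASU01085875.1 had 15.97 ± 4.58 CPM in winter and 4.06 ± 0.84 in summer (SD, n = 6 each), a log2 fold change of 1.95 (SE 0.22, adjusted p = 0.024), and GASU01045791.1 rose by 1.68 (SE 0.23, adjusted p = 0.047). GASU01083688.1 fell from 40.7 ± 12.0 CPM in summer to 8.29 ± 1.36 in winter, a log2 fold change of -2.28 (SE 0.24, adjusted p = 0.024), and GASU01080817.1 had a log2 fold change of -1.95 (SE 0.23, adjusted p = 0.031). DESeq2 called 1058 contigs for season, and edgeR with the code number in place of the nursery called 1986 (933 higher, 1053 lower in winter), the 7 among them. Leaving out 1 library moved the count between 0 and 514, the latter without cold replicate 1.

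Between the Lower Keys and Miami labels edgeR called 0 host contigs (173 at an unadjusted p under 0.05, where 1061 lie under it by chance alone, and 0 by DESeq2). In the 8 ambient and hot libraries, where labels and code numbers go together, 157 host contigs differed between nurseries, 87 of them higher in the libraries labelled Lower Keys. The labels say that the nurseries share no genets, so nursery and genets cannot be told apart. Grouped by code number, all 12 libraries gave 3353 contigs, 1437 higher and 1916 lower in code 2. Libraries that share corals count as separate replicates in these tests too. The temperature by nursery interaction was called in 290 host contigs by label and 0 by code number. By label DESeq2 called 3141, and scaling to the total over all contigs gave 131. Leaving out 1 library gave 35, 78 and 98 without cold replicates 2, 4 and 1, 101 to 181 without ambient replicate 1, 2 or 3 or hot replicate 1, 2 or 3, and at most 385. Its cold term had 931 calls and its hot term 0 (989 at an unadjusted p under 0.05).

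**Figure D2:**
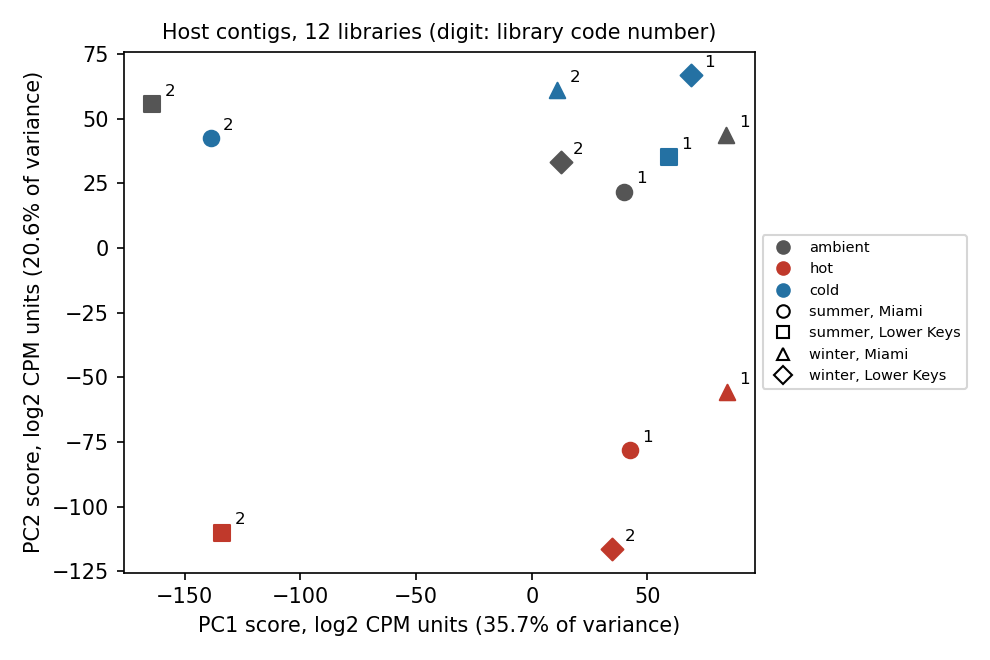
Principal component scores of the 12 libraries from host log2 CPM, with colour for temperature, marker shape for season and nursery label and the digit for the library code number. The 3 summer libraries with code number 2 lie apart at PC1 scores of -134 to -164, and the 4 hot libraries lie at -55.6 to -116 on PC2.

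Temperature accounted for 27.9% of the variance of host log2 CPM (permutation p = 0.051), season for 15.9% (permutation p = 0.078) and nursery by label for 5.54% (permutation p = 0.87). The adjusted permutation p over the 3 factors was 0.12, 0.12 and 0.87. Permuted libraries gave median shares of 17.7% for temperature, which has more levels, 7.83% for season and 7.88% for nursery, so the raw shares are not directly comparable. By code number the share was 22.1% (permutation p = 0.0025, chosen after seeing the data). The permutations took all libraries as independent, although libraries of one season and nursery share corals. In the symbiont, temperature accounted for 20.6% (permutation p = 0.23), season for 17.7% (permutation p = 0.022, adjusted 0.067) and nursery by label for 7.12% (permutation p = 0.82). By code number the symbiont share was 12.6% (permutation p = 0.098, also chosen after seeing the data). Permuted libraries gave symbiont medians of 17.3% for temperature, 8.11% for season and 8.10% for nursery.

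The symbiont's share of the counts fell in heat in all 4 matched pairs. The ratio of symbiont to host counts was 2.95-fold lower in the hot than in the ambient libraries, a mean log2 difference of -1.56 ± 0.52 (SD, n = 4 pairs; two-sided exact permutation p = 0.13, the smallest that 4 pairs allow, adjusted 0.625 over 5 comparisons). With libraries permuted without pairs, the two-sided exact p was 0.029, also the smallest possible, and 0.14 after adjustment. The cold and ambient ratios differed by -0.03 ± 0.70 (SD, n = 4 pairs; exact permutation p = 1), which is under the spread between pairs. Between hot and cold the difference was -1.53 ± 1.14 and lower in 3 of 4 pairs (exact permutation p = 0.25, n = 4). These pairs rest on the nursery labels of the cold libraries, and paired by season and code number, chosen after seeing the data, it was -1.53 ± 0.93 and lower in 4 of 4 pairs (exact permutation p = 0.13, the smallest possible). Winter and summer differed by 0.19 ± 0.88 (exact permutation p = 0.66, n = 6 pairs) and the nursery labels by -0.01 ± 0.65 (exact permutation p = 1, n = 6 pairs). These 6 pairs are not independent, since libraries of one season and nursery share corals.

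The fall was uneven within the symbiont table. The 10 symbiont contigs with the highest counts over all libraries held 5.67% ± 1.22 of all counts in the ambient and 4.86% ± 1.05 in the hot libraries, a mean log2 difference of -0.22 ± 0.48 (SD, n = 4 pairs; exact permutation p = 0.63). The other symbiont contigs held 10.8% ± 2.71 and 2.87% ± 1.81, a 4.18-fold fall with a mean log2 difference of -2.06 ± 0.65 (n = 4 pairs, exact permutation p = 0.13, the smallest possible).

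**Figure D3:**
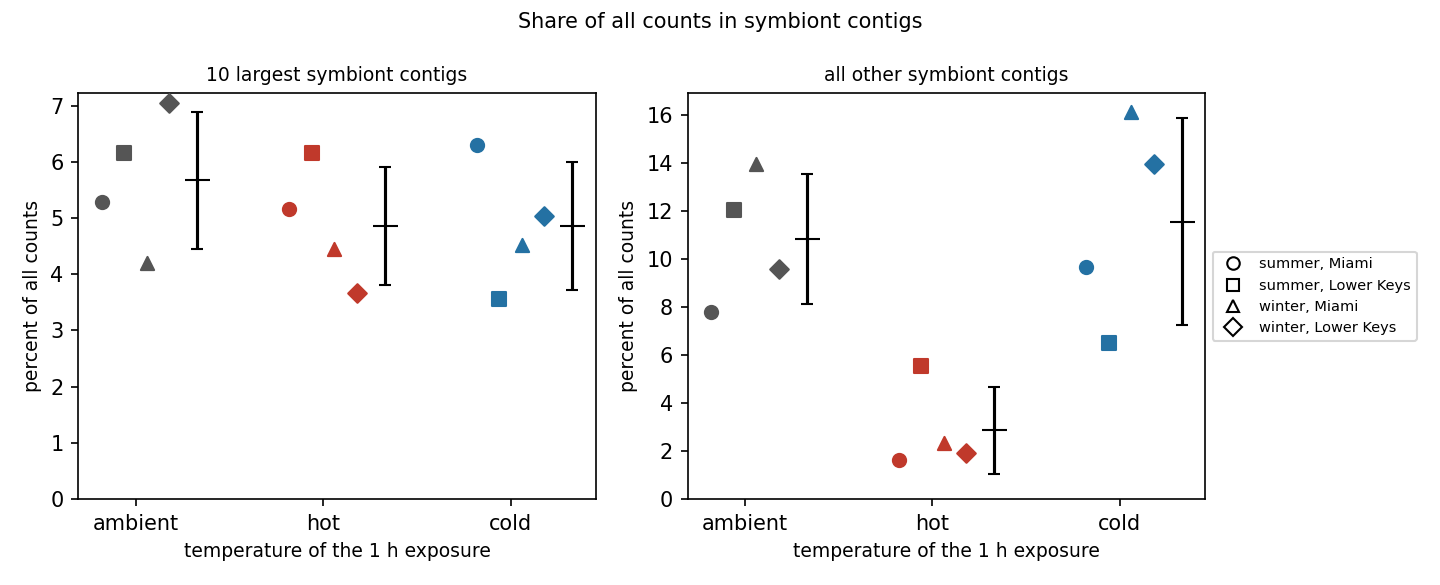
Percent of all counts of each library in the 10 largest symbiont contigs and in all other symbiont contigs, by temperature; points are libraries, bars the mean and SD of 4 libraries. The hot libraries lie at 1.64% to 5.55% for the other contigs, under every ambient and cold library, while the 10 largest contigs overlap between temperatures.

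Within the symbiont table, scaled to its own contigs, few contigs were called for temperature. Heat called 3 of 20656 by edgeR, all higher (1017 at an unadjusted p under 0.05, 88 by DESeq2). With temperature as the only term edgeR called 0, as it did without ambient replicate 2, 3 or 4, hot replicate 3 or 4 or cold replicate 4. It called 1 without ambient replicate 1, hot replicate 1 or cold replicate 3, 2 without cold replicate 1 and 14 without hot replicate 2. GASU01030479.1 rose from 121 ± 38.7 to 956 ± 739 CPM of symbiont counts (SD, n = 4 each), a log2 fold change of 2.94 (SE 0.42, adjusted p = 0.042). GASU01030268.1 rose by 2.60 (SE 0.36, adjusted p = 0.042). Relative to the total of all contigs neither was called, with log2 fold changes of 0.66 and 0.38, and 16590 symbiont contigs were called lower and 0 higher. With symbiont library totals in place of TMM factors 12 were higher and 4496 lower. Cold called GASU01040437.1 alone, from 30.997 ± 8.89 to 81.4 ± 25.8 CPM, a log2 fold change of 1.38 (SE 0.17, adjusted p = 0.019). That call ended with the replicate block and on leaving out any of 8 of the 12 libraries. The contig stood at 84.6 ± 22.2 CPM in the hot libraries, so its level was not particular to cold. For cold against ambient 101 symbiont contigs had an unadjusted p under 0.05, where 1033 lie under it by chance alone. Between hot and cold edgeR called 0 (978 at an unadjusted p under 0.05, 73 by DESeq2).

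Season cannot be told apart from its collection, and libraries of one season and nursery share corals. Between winter and summer edgeR called 12 symbiont contigs, 3 higher and 9 lower in winter, with 4049 at an unadjusted p under 0.05. The split depended on the scaling, with 1 higher and 0 lower with symbiont library totals in place of TMM and 4 higher and 0 lower with the total over all contigs, at median log2 fold changes over all contigs of 0.42 and 0.54 against 0.12 with TMM. Leaving out 1 library gave 965 calls without ambient replicate 1, 908 without cold replicate 1, 20 without hot replicate 1 and 0 to 4 without any other. GASU01050184.1 rose from 6.00 ± 5.75 CPM in summer to 41.3 ± 10.7 in winter (SD, n = 6 each), a log2 fold change of 3.18 (SE 0.35, adjusted p = 0.0065), and GASU01056538.1 rose by 1.77 (SE 0.28, adjusted p = 0.038). GASU01062612.1 fell from 81.6 ± 32.7 to 20.4 ± 3.03 CPM, a log2 fold change of -1.97 (SE 0.28, adjusted p = 0.026), and GASU01072470.1 had a log2 fold change of -1.86 (SE 0.27, adjusted p = 0.026). DESeq2 called 1515, and with the code number in place of the nursery edgeR called 1848 (433 higher, 1415 lower), the 12 among them. No symbiont contig was called between nursery labels by edgeR (233 at an unadjusted p under 0.05) or DESeq2, and 587 were by code number. In the 8 ambient and hot libraries, where label and code number go together, edgeR called 0 (2125 at an unadjusted p under 0.05). Tested over both temperatures together, the interactions of temperature with season and with nursery gave 0 symbiont calls by edgeR (525 and 2841 at an unadjusted p under 0.05, 28 and 1719 by DESeq2). By chance alone 1033 lie under it, so the tests of the season interaction and of the nursery labels were conservative. The cold term of the nursery interaction taken alone had 84 calls and the hot term 0 (1367 at an unadjusted p under 0.05).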

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

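The test of the contigs in neither table was set before its result was seen. The other tests in this part were chosen after the result they bear on, and the prediction for the counts of other splits was written down after those counts had been seen.

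The first pattern is that the cold libraries go with the library code number and not with their nursery label. By label, 290 host contigs had a temperature response that differed between nurseries, a test of the difference itself, and by code number 0 did. The 290 varied from 35 without cold replicate 2 to 385 on leaving out 1 library (78 and 98 without cold replicates 4 and 1, 101 to 181 without ambient replicate 1, 2 or 3 or hot replicate 1, 2 or 3), and DESeq2 called 3141. Nursery and genets cannot be told apart, so marks of a nursery may be marks of its genets. In each season, contigs with at least 50 counts in one ambient library and at most 3 in the other were taken as such marks (534 over both seasons). Of these, 85.0% differed the same way between the 2 hot libraries and 91.8% the opposite way between the 2 cold libraries, with a median log2 ratio of 2.72 in the hot and -3.09 in the cold, so exchanged nursery labels are a candidate explanation, of the cold libraries or of both other temperatures, and the values do not say which. A cold response that depends on the nursery would have kept most of these contigs on their side, whereas at least 80% were reversed in each season, and a batch of 3 consecutively numbered libraries would leave the difference between code numbers unrelated between seasons, whereas it correlated at 0.43 across host contigs (0.13 by label). That counts against such batches as the whole account. A batch effect on top stays open for the summer libraries with code number 2, since 459 of the 534 contigs are from summer and 75 from winter, the log2 difference between code numbers had an SD of 1.32 across host contigs in summer and 0.78 in winter, and these 3 libraries alone lie apart on the first principal component.

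The second pattern is the smaller share of symbiont contigs in the hot libraries. A few contigs taking most of the symbiont counts would account for little of it, since without the 10 largest contigs of each partner the log2 difference grew from -1.56 to -2.21. Dilution by host RNA and fewer symbiont cells both lower all symbiont contigs alike, but the 10 largest changed by 1.84 ± 0.72 less on the log2 scale than the others (SD, n = 4 pairs, 4 of 4 above 0). The cold libraries alone choose the same 10, and the 10 largest of the ambient libraries alone, 9 of them shared, changed by 1.76 ± 0.70 less, so the choice with the hot libraries included does not make the difference. The contigs ranked 11 to 100 had a median log2 ratio of hot to ambient of -2.07 relative to all counts, with 98.9% of them lower. Of the 10 largest, 5 were higher in the hot libraries. If these 10 are symbiont contigs, neither can be their whole account. How contigs were assigned to a partner is not given, so that condition was not checked. The contigs ranked 1 to 10 had a median log2 ratio of 0.06 relative to all counts. That is nearer the median of the host contigs (-0.19) than that of the symbiont contigs (-2.25). For the other contigs, of which 99.6% were lower relative to all counts (quartiles -2.78 and -1.93), dilution, a loss of cells and a biological fall of symbiont transcripts at 35 °C cannot be told apart, because the tables hold relative amounts only.

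The third pattern is the signal in the 51523 contigs that neither the host nor the symbiont table holds and that no comparison of the report used. Tested in the same way, 3614 of 47213 differed between hot and ambient (2876 higher, 738 lower), 9 between cold and ambient and 2929 between hot and cold by edgeR. Scaled to the total over all contigs, the split between hot and ambient reversed, with 767 higher and 16629 lower, and between hot and cold 837 were higher and 18425 lower. Relative to all counts, 56.2% of them had a hot to ambient ratio nearer the symbiont median (-2.25) than the host median (-0.19), against 96.0% of symbiont and 13.7% of host contigs. The median ratio of the contigs in neither table was -1.62. A mixture of contigs of both partners would give such values, but so would a single group lying between the 2 partner medians. The test cannot tell these apart. Nothing was checked on sequences, and other organisms of the tissue stay open.

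The 3 host temperature counts as fitted with all 12 libraries were the highest among splits that take no account of the pairing. This does not exclude chance, since the libraries are paired and several comparisons were tested without correction. The real split was the only 1 of 35 splits of the 8 libraries with as many contigs for hot against ambient (1288, highest other 584), cold against ambient (249, highest other 7) and hot against cold (1494, highest other 0). Of the 8 splits that part every matched pair by nursery label, the real split also had the most contigs (highest others 0, 7 and 0), but 8 splits are too few for a share under 0.05. This was tested for that fit alone, and for cold against ambient the 8 compared libraries by themselves gave 0 calls by edgeR, and 14 were left without cold replicate 4. The split with 584 parts the Miami from the Lower Keys libraries of the ambient and hot groups. For host season calls 2 of 40 drawn splits of the 12 libraries, the real one included, gave at least the real 7 (highest other 3264). For the host nursery labels, with 0 calls, the count decides nothing, since all 40 splits have as many (highest other 0). In the symbiont 2 of 35 splits gave at least the 3 contigs for hot against ambient (highest other 3), and 2 of 35 at least the 1 for cold against ambient, the real split included each time. Of those 35 the highest other, 422, parts code number 1 from code number 2. For symbiont hot against cold, with 0 calls, all 35 have as many (highest other 0), which again decides nothing. For symbiont season 2 of 40 splits, the real one included, gave at least the real 12 (highest other 2244), and for the nursery labels all 40 have as many as 0 (highest other 0). Chance was thus not excluded for season or for the symbiont counts of hot and of cold against ambient, nor for the host temperature counts with the pairs kept. The season splits with 3264 and 2244 calls are the same split, which parts the ambient and cold libraries of summer with code number 2, with all hot libraries, from the other ambient and cold libraries, and so points to a structure of the samples.

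Among 104 groups of 4 libraries examined for a single library far from its group, 6 had one, where chance gives about 5.2. The ambient summer Lower Keys library had 48244845 counts against 37038439 to 38850490 in the other ambient libraries. The hot summer Lower Keys library had 20964767 host counts against 22858151 to 23180850. Contigs risen in heat held 42.2% of host counts in the hot winter Lower Keys library against 30.0% to 31.9%, and 8.69% in the summer cold library labelled Lower Keys against 5.82% to 6.11% in the other cold libraries. Those risen at least 8-fold held 2.14% in the ambient summer Miami library against 1.04% to 1.16%. GASU01049002.1 had 0.068 CPM in the hot winter Lower Keys library and 0 in the other hot libraries.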

How the results depend on the processing

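The library code number as nursery, the block by season and code number, the ambient and hot libraries alone, the total over all contigs, the pairs by code number, the choice of the 10 largest symbiont contigs without the hot libraries and the splits that part every pair were chosen after seeing the data; the other settings were set before. No named contig changed direction under any setting run. Over planned settings named contigs kept their call in 304 fits and lost it in 161, and over added ones in 51 and 18. The cause of the changes below was not tested. Depth limits single symbiont contigs in the hot libraries, with a median of 10 to 27 counts, and its effect on the calls was not tested.

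DESeq2 called 2607 host contigs for hot against ambient, 1123 for cold against ambient, 3073 for hot against cold, 1058 for season, 17 for temperature by season and 3141 for temperature by nursery. In the symbiont it called 88, 3, 73, 1515, 28 and 1719 in the same order. It called all 1288, 249 and 1494 of edgeR's host temperature contigs. Library totals without TMM gave 4267, 121 and 7247 host contigs for the 3 temperature comparisons and 4508, 0 and 7367 symbiont contigs, with 1 for symbiont season. DESeq2 size factors in edgeR gave 5 symbiont contigs for hot against cold and 29 for season, and the fit without the robust step gave 1 for hot against ambient. The factor compared as the only term, with no replicate block, gave 145 host contigs for cold, 0 and 0 symbiont contigs for hot and for cold, and 633 for symbiont season. The 8 compared libraries alone gave 0 host contigs for cold and 1 and 0 symbiont contigs for hot and cold against ambient.

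The replicate block of season-by-nursery strata called 54 host and 0 symbiont contigs for cold against ambient, and it moved no other total by over 1.5 times, while the host falls went from 614 to 385 for hot against ambient and from 517 to 316 for hot against cold. The season-by-code-number strata as replicate block gave 3810 host contigs for hot, 1682 for cold and 4461 for hot against cold. They hold 1287 of the 1288, all 249 and 1492 of the 1494. The code number as nursery gave 2607, 965 and 3195 host contigs for the temperature comparisons, 1986 for season, 3353 for nursery and 0 for temperature by nursery (1282 of the 1288 and all 249 kept), and 1, 1848 and 587 symbiont contigs for hot, season and nursery. The overlap of hot and cold calls was then 88 higher in both, 212 lower in both and 49 opposite, and at an unadjusted p under 0.01 by label it was 79, 212 and 49. The ambient and hot libraries alone gave 0 host contigs for season, 157 for nursery and 0 symbiont contigs for season. The total over all contigs gave 88 host contigs for cold, 131 for temperature by nursery, and 16590, 0, 17355 and 4 symbiont contigs for hot, cold, hot against cold and season.

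Leaving out each library in turn gave 429 to 1445 host contigs for hot against ambient (429 without hot replicate 4, and 528 to 770 without ambient replicate 2, 3 or 4 or hot replicate 1, 2 or 3). Cold against ambient gave 14 to 271 (14 without cold replicate 4, 35 and 36 without ambient replicates 1 and 3, 89 and 91 without cold replicates 3 and 2, 125 to 152 without hot replicate 1, 3 or 4). Hot against cold gave 585 to 1716 (585 without hot replicate 4, 694 and 708 without cold replicates 3 and 4, 818 and 923 without hot replicates 2 and 1). Host season gave 0 to 514, with 514 without cold replicate 1 and 7 only without hot replicate 1. Temperature by nursery gave 35 to 385 (35, 78 and 98 without cold replicates 2, 4 and 1, 101 to 181 without ambient replicate 1, 2 or 3 or hot replicate 1, 2 or 3). Symbiont counts ran from 0 to 14 for hot against ambient (14 without hot replicate 2, and 0 or 1 without any ambient library, hot replicate 1, 3 or 4 or cold replicate 3 or 4) and from 0 to 1 for cold. They ran from 0 to 13 for hot against cold (13 without hot replicate 2, 8 without ambient replicate 4), 0 to 965 for season and 0 to 1 for temperature by nursery (1 without hot replicate 3). Symbiont season reached 965 without ambient replicate 1 and 908 without cold replicate 1, gave 20 without hot replicate 1, and lay at 0 to 4 without any other library. Host nursery and temperature by season stayed at 0. The host nursery share of variance ran from 4.74% to 10.0%, and the host temperature share over the 500 most variable contigs was 33.8% (permutation p = 0.030). The log2 symbiont to host ratio in heat ran from -1.76 to -1.40 without single pairs and was -2.21 without the 10 largest contigs of each partner. Fewer libraries also mean fewer degrees of freedom. The tests of gene lists with camera and fry were not run, since no contig could be matched to a gene name.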

Other observations

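The test of seasonal levels and a first test of levels in the cold were set before their results were seen, and the test with divided ambient libraries was chosen after the first test in the cold had been seen.

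A small group of host contigs that rose in heat held a large part of the host counts of the hot libraries. The 122 contigs that rose at least 8-fold held 1.37% ± 0.52 of host counts in the ambient libraries, 20.7% ± 4.47 in the hot and 1.04% ± 0.44 in the cold (SD, n = 4 each). Summer and winter responses to heat correlated at 0.52 across all tested host contigs (Spearman) and those to cold at 0.37, against 0.11 and 0.03 in the symbiont, where contigs are not independent and each pair of responses shares the fit.

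A hypothesis was that contigs raised by heat stand higher in summer before any treatment, as a standing preparation for warm water. Over the 674 risen contigs the median log2 difference of summer minus winter in the ambient libraries was -0.045, at the low end of 10000 random lists matched on mean expression (central 95% from 0.01 to 0.11), with 315 of 674 above 0. For the 122 with at least 8-fold rises it was -0.28 (random lists -0.17 to 0.13). Their share of host counts was 2.14% and 1.16% in the 2 summer and 1.04% and 1.14% in the 2 winter ambient libraries for those risen at least 8-fold. For all 674 the share was 8.36% and 5.04% in summer and 6.78% and 7.40% in winter. The median contig thus stood no higher in summer. The share of the 122 stood clearly higher only in the summer Miami library (2.14%), and the other summer library (1.16%) lay near the winter ones. The share of the 674 overlapped between seasons, and all these values describe only 2 ambient libraries per season.

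A further hypothesis was that these contigs may also rise in the cold. In the first test the 674 risen contigs had a median log2 difference of cold minus ambient of 0.06 (random lists -0.07 to 0.01), which met the prediction. For the 122 risen at least 8-fold it was 0.23 (random lists -0.10 to 0.11). For the 614 fallen contigs it was -0.42 (random lists -0.01 to 0.08). But the risen contigs had been chosen for low levels in the same ambient libraries, which raises their median by itself. The fallen ones had been chosen for high levels there, which lowers theirs. For the risen contigs the ambient libraries were then divided. A single division was used, with each part choosing the contigs in turn. The 674 contigs highest in the hot libraries were chosen against one part and measured as cold minus the other part. Chosen with ambient replicates 1 and 4, their median log2 difference was 0.30 (random lists 0.05 to 0.19). Chosen with replicates 2 and 3, it was -0.22 (random lists -0.08 to 0.03). The direction thus depended on which ambient libraries chose and which measured, and no general rise in the cold was seen.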
